A study of Mus musculus with 8 samples.

How the data were processed

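RNA from dispase-separated epidermis of CD1 mouse back skin was made into stranded, polyadenylated RNA libraries and sequenced as 100-bp paired-end reads on an Illumina HiSeq instrument. There were 8 libraries, 2 for each combination of labelled Ovol1 genotype and IMQ treatment, 1 from a female and 1 from a male. Per the labels the processing used Trimmomatic 0.35, STAR 2.5.2a, DESeq2 1.24.0, R 3.6.1 and the mm10 genome; the read counter, the gene annotation and the filter on genes are not given in the sources used here. The deposited values are a signal in arbitrary units, read counts divided by 1 size factor per library, in 2 tables (untreated and IMQ) of the same 16902 gene symbols, each table scaled by itself. All values of each library were whole multiples of 1 step within 0.001 read, and dividing by it gave whole reads, 28.6 to 43.1 M per library, which is called recovered reads. Genes with few reads, such as Il17a with fewer than 10 in several libraries, carry a counting error that greater depth would lower. Gene positions are from the GENCODE vM21 annotation of GRCm38, which held 16745 of the symbols.

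Genotype effects were tested with limma 3.58.1 in R 4.3.3 on log2 of the deposited value plus 1. Genes needed a mean of at least 10 over the 4 libraries of either table, which left 14614. The fit held 4 group means over all 8 libraries, so the tables share 1 estimate of the spread (4 residual degrees of freedom), with moderation by trend and robust fitting. The contrasts were labelled knockout minus control untreated, the same under IMQ, and the difference of these. Each lies within a table or is a difference of such values, so the separate scaling cancels. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Replicate numbers follow sex, and deviations from group means correlated between groups by sex (0.145 to 0.463 across genes, 0.0744 to 0.394 without genes on X and Y), so counts with sex as a block stand beside the main ones. Group, contrast, test, alternatives, gene lists and the rule for naming genes were fixed before the data were examined.

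There were 37 gene lists written from general knowledge of epidermal layers, keratinocyte activation, inflammation, other skin cell types, cell processes and RNA quality. Listed symbols absent from the tables were matched through official synonyms, with a correction to this step made after first results were seen that took Krt1 out of the hair shaft list. The 34 lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists of a contrast. Alternatives were an estimated correlation and fry, which tests whether a list moves on balance without comparing it with other genes. Named genes were Ovol1 and Ovol2, the 10 largest rises and falls past the threshold with 1 direction in both sexes, the 5 smallest p per direction where fewer than 5 passed, and up to 4 members per list with an unadjusted p under 0.05 and the largest changes; predicted genes and pseudogenes were not named, and 2 genes that met the rule are not reported here. The split of the Lce and Sprr list by subfamily, Ap5b1 and Ehbp1l1, and Lce3e and Sprr2f were chosen after their values were seen.

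A Fisher test on the genes called in both contrasts was planned but left out, as limma called 0 in untreated epidermis (652 at an unadjusted p under 0.05; edgeR 0 and DESeq2 90). IMQ was set against untreated as CPM of recovered reads with TMM factors over 8 libraries and an added 0.5, without a test. Other settings were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, TMM and quantile scaling, plain moderation, each table alone, sex as a block over or within tables, edgeR 4.0.16 (quasi-likelihood, with and without the block) and DESeq2 1.42.0 on recovered reads, an adjusted p under 0.10, a fold of at least 2, and each library left out, where the lone library of a group is assumed to vary like the others. The fibroblast covariate (mean log2 value of the dermal fibroblast list), leaving out each library with the block and leaving out each library for IMQ against untreated were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the plots. The pipeline was tested on simulated counts with 200 changed genes per contrast. Of genes changed 4-fold, limma recovered 75% untreated, 80% under IMQ and 62.5% for the difference, against 21%, 31% and 7.5% at 2-fold, with 9 false calls among 105, 126 and 152. For a simulated list shifted by 1 on the log2 scale camera gave an adjusted p of 2.21e-17 with the preset and 0.0607 with the estimated correlation. It called 0 of 33 random lists. The simulated genes were drawn independently of each other, so the preset was not tested on lists whose genes vary together. The simulation also held no difference between the sexes. With sex as a block limma made 124 calls there under IMQ against 126 without it, but 358 against 64 in the data. The simulated recovery and false calls may therefore not carry over to these libraries.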

Results

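Gene expression was measured by RNA sequencing of polyadenylated RNA in the epidermis of CD1 mouse back skin, freed from the dermis with dispase. The mice differed in Ovol1, a zinc-finger transcription factor of stratified epithelia, and in treatment with imiquimod (IMQ), a Toll-like receptor agonist that gives a psoriasis-like inflammation when applied to mouse skin. The 8 libraries formed 4 groups of 2, and each group held 1 female (replicate 1) and 1 male (replicate 2). The untreated groups were Ovol1 +/- controls and mice labelled Ovol1 -/-, and the IMQ groups were Ovol1 +/+ controls and mice labelled Ovol1 -/-. The control genotype therefore differed between the untreated and the IMQ comparison. The female and male libraries held 43.1 and 33.7 M reads in the untreated controls and 35.2 and 34.9 M in the untreated labelled knockouts. Under IMQ they held 33.1 and 28.6 M in the controls and 31.4 and 34.0 M in the labelled knockouts. Between 16249 and 16603 of 16902 listed genes had a read in each library. Because each group held 1 female and 1 male, the p-values measure the spread between these particular libraries. Xist was at 19844 to 56634 normalised counts in the 4 libraries labelled female and at 38.8 to 64.9 in the 4 labelled male, and Ddx3y was at 2.07 to 4.32 and at 3698 to 5026 in turn. The first principal component of the log2 deposited values held 66.3% of the variance and set all 4 IMQ libraries apart from the 4 untreated ones. The separate scaling of the tables may be part of it. Between them the median gene was shifted by -0.32 in the labelled knockouts and -0.26 in the controls.

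Ovol1 itself (chromosome 19, 5549136 to 5560646, minus strand, mm10) was read in every library and stood higher in the libraries labelled knockout. In untreated epidermis its normalised counts were 16629 and 14582 in the controls and 27433 and 26601 in the labelled knockouts. Under IMQ they were 7635 and 9556 in the controls and 13457 and 13077 in the labelled knockouts. The log2 fold change of labelled knockout against control was 0.79 (SE 0.15, limma adjusted p = 0.346) untreated and 0.64 (SE 0.15, adjusted p = 0.0880) under IMQ, so neither passed the threshold of 0.05. With the sex of the animals as a block the adjusted p was 0.228 and 0.0681. Ovol2, the paralog of Ovol1, had log2 fold changes of 0.67 (SE 0.27, adjusted p = 1.00) and 0.64 (SE 0.27, adjusted p = 0.224). The tables give 1 value per gene and none per exon, so the Ovol1 values do not check the genotype labels, and the -/- libraries are called labelled knockouts throughout.

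**Figure D1:**
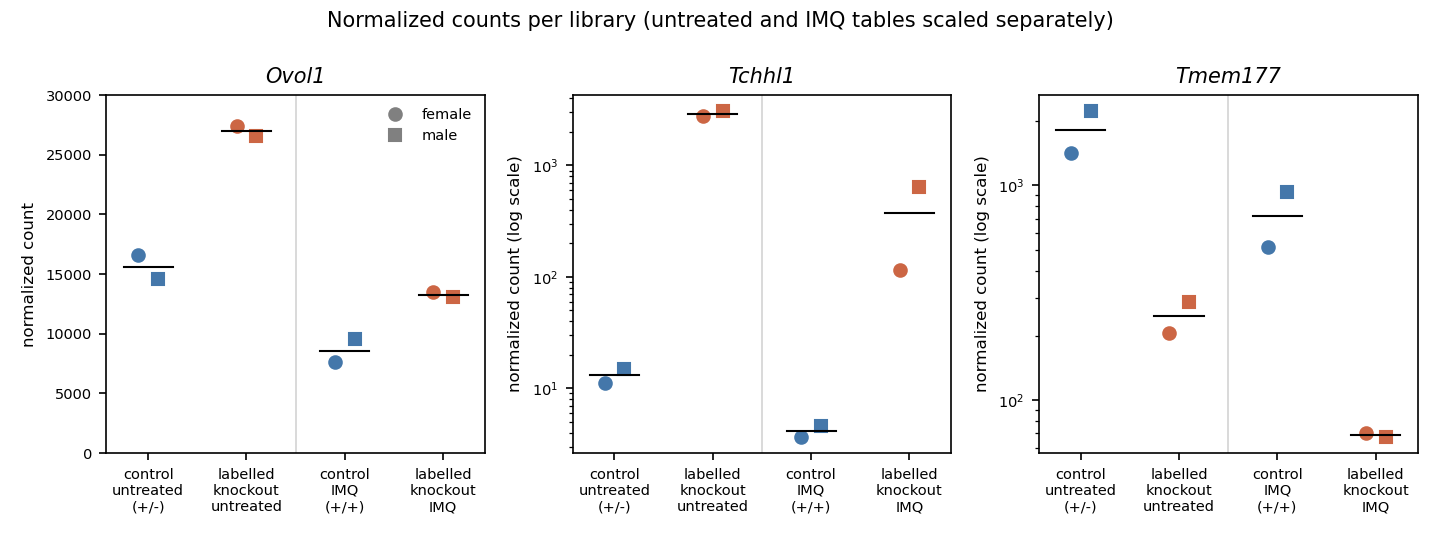
Normalised counts per library of Ovol1 (linear axis), Tchhl1 and Tmem177 (log axes) in the 4 groups, with circles for females, squares for males and lines for group means; the untreated and IMQ tables were scaled separately. The 4 labelled knockout libraries lay between 13077 and 27433 for Ovol1, and each stood above both controls of its own table.

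The untreated comparison asks how labelled loss of Ovol1 alters the epidermis at rest. Tchhl1, a trichohyalin-like gene of the epidermal differentiation complex, showed the widest separation: 13 and 14 reads in the controls against 2689 and 2976 in the labelled knockouts (log2 fold change 7.71, SE 0.68, limma adjusted p = 0.0634, n = 2 per group). Psca, which encodes a surface antigen of epithelial cells, was at 31.4 ± 16.3 normalised counts in the controls and 1992 ± 691 in the labelled knockouts (SD, n = 2). Itga9, an integrin subunit gene, had a log2 fold change of 3.68 (SE 0.40), the RNA gene Snhg11 3.39 (SE 0.34) and Alpk1, a kinase of innate sensing, 2.02 (SE 0.21). All of these had the same adjusted p of 0.0634. Itga9 rested on few reads, 5 and 6 in the controls and 72 and 83 in the labelled knockouts. On the lower side, Tmem177, a mitochondrial membrane protein gene, was at -2.86 (SE 0.33, adjusted p = 0.0634). Behind it came Ces2f, a carboxylesterase gene, at -2.61 (SE 0.51), Tnfrsf11b, which encodes the decoy receptor osteoprotegerin, at -1.67 (SE 0.32), and the matrix protein genes Thbs2 at -0.94 (SE 0.17) and Ccn1 at -0.71 (SE 0.14), with adjusted p of 0.346 to 0.358. None of these genes passed the threshold. With sex as a block Tchhl1 and Tmem177 did (adjusted p = 0.0312), as did Snhg11, Psca and Alpk1 (0.0404). Without the female (7.75e-04) or male labelled knockout IMQ library (0.00108) Tchhl1 passed, and without the female (0.0394) or male control IMQ library (0.0354) Snhg11 did.

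Of the 34 gene lists tested, 4 were called higher and 3 lower in the untreated labelled knockouts with camera's preset correlation, while the adjusted p of each was 0.892 to 0.895 with an estimated correlation. Members of the sebaceous gland list stood higher in the labelled knockouts in 14 of 15 cases, with a median log2 fold change of 0.81 (camera adjusted p = 2.86e-04, 0.285 without the female control), and Elovl5 and Soat1, which act in fatty acid elongation and sterol esterification, were at 1.00 (SE 0.41) and 0.81 (SE 0.35). Markers of T cells were positive in 14 of 15 cases with a median of 0.25 (adjusted p = 0.00302, 0.451 without the female control), and the cytokine receptor gene Il2ra was at 0.90 (SE 0.35). The oxidative stress list had 12 of 15 positive members and a median of 0.18 (adjusted p = 0.0240), with the glutathione transferase genes Gsta4 at 1.68 (SE 0.42) and Gsta3 at 1.01 (SE 0.33). Its call was lost without the female control (0.0566), the male control (0.282) or the female labelled knockout (0.191). The list of the IL-17, IL-22 and IL-23 axis had 12 of 18 positive members and a median of 0.12 (adjusted p = 0.0497, 0.0516 with quantile normalisation). That call was lost without the male control (0.388), the female labelled knockout (0.580), the female (0.0963) or male control (0.0988) under IMQ, or the female (0.0519) or male labelled knockout (0.0529) under IMQ. Il20, Il17a and Il17f, cytokines of that axis, were at 2.90 (SE 0.58), 2.33 (SE 0.94) and 1.66 (SE 0.47). The IL-17 genes were at low counts, with 6 and 0 reads of Il17a in the controls and 20 and 6 in the labelled knockouts. Interferon response genes were negative in 21 of 28 cases, with a median of -0.28 (adjusted p = 0.0119, 0.879 without the male control), and Usp18 was at -1.02 (SE 0.44). Ifit3b had 4 and 5 reads in the controls and is listed at 0 in both labelled knockouts. Hair follicle stem and outer root sheath genes were negative in 13 of 17 cases, with a median of -0.24 (adjusted p = 0.0188), Cd34 being at -0.58 (SE 0.23) and Dkk3 at -0.57 (SE 0.21). That call was lost without the female control (0.0683), the male control (0.153) or the female labelled knockout (0.114). The basal keratinocyte list had 14 of 16 negative members and a median of -0.12 (adjusted p = 0.0452), which was -0.30 in the female pair and 0.02 in the male pair. Dst, an anchor of hemidesmosomes, was at -0.44 (SE 0.15). The basal list was not called with quantile normalisation (0.178) or on recovered reads (0.0639), without the male labelled knockout (0.473) or either control under IMQ (0.0671, 0.0673), and without the female control its direction turned up (0.451).

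No member of these 7 lists was called over all genes. Adjusted over the list alone, 1 gene of the IL-17, IL-22 and IL-23 axis was higher, 1 interferon gene was lower, and the other 5 lists had 0. The remaining 27 lists tested had adjusted p of 0.0887 to 0.958. Among them, chemokine genes outside the neutrophil group had a median of -0.27, with the dendritic cell chemokine Ccl22 at 2.29 (SE 0.61), and the barrier lipid list had a median of 0.09, with the lipase gene Lipk at -1.32 (SE 0.31). Markers of dermal fibroblasts had a median of -0.41 (-0.68 in the female pair and -0.06 in the male pair, adjusted p = 0.0887, 0.0159 with sex as a block). The normalised count of Col1a1, a fibroblast collagen gene, was 994 and 5356 in the female and male controls and 435 and 5771 in the labelled knockouts. The 3 lists with fewer than 5 tested members had medians of 0.06 for mast cells and basophils, 0.06 for haemoglobin genes and 0.19 for histones.

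In limma, 0 of 14614 genes passed the threshold in untreated epidermis, and 652 had an unadjusted p under 0.05 where 731 would by chance. The edgeR test also called 0 genes (656 at an unadjusted p under 0.05), and DESeq2 called 90 (65 higher, 25 lower). With sex as a block limma called 8 (6 higher, 2 lower) and edgeR 6. At an unadjusted p under 0.05 they then had 865 and 876 genes, above the 731 and 739 that would by chance. Whether the untreated effect exceeds chance at that level thus depends on the block. Quantile normalisation gave 9 calls, each table alone 8, a pseudocount of 5 gave 5 and an adjusted p under 0.10 gave 15. Leaving out any 1 of the 4 IMQ libraries gave 2 calls. Of the lists, 11 were called with sex as a block (also IL-1 family, other chemokines, epithelial-mesenchymal transition and dermal fibroblasts, with adjusted p of 0.0159 to 0.0469) and 0 by fry, and 3 to 12 when 1 library was left out, with 4 without the female control, 3 without the male control and 12 without the male labelled knockout.

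The comparison under IMQ asks how labelled loss of Ovol1 alters the inflamed epidermis, and it gave 64 genes past the threshold (23 higher and 41 lower in the labelled knockouts). Of the 14 tested cornified envelope genes of the Lce1 family, 5 were called lower. Among them Lce1b fell from 4414 ± 2045 normalised counts in the controls to 426 ± 293 in the labelled knockouts (SD, n = 2), a log2 fold change of -3.48 (SE 0.49, limma adjusted p = 0.0439). Il1a, an alarm cytokine of keratinocytes, rose from 1204 ± 144 to 4376 ± 341 normalised counts (1.86, SE 0.18, adjusted p = 0.0221), and Gjb6, a connexin gene, from 417 ± 23.9 to 1676 ± 391 (1.99, SE 0.20, adjusted p = 0.0221). The chromosome 3 gene Rptn, which encodes the cornified envelope precursor repetin, rose from 307 ± 76.0 to 1950 ± 683 (2.64, SE 0.34, adjusted p = 0.0400). All 64 genes moved the same way in the female and in the male pair. The test itself requires this, since pairs of opposite direction would give too wide a spread for a call. Without any 1 of the 4 untreated libraries, which enter the IMQ contrast only through the spread, limma called 0 genes. Without the female control IMQ library 5 were called (2 of the 64), without the male 49 (14 of the 64), without the female labelled knockout 3 (2 of the 64) and without the male 299 (53 of the 64). With sex as a block limma called 358 (86 higher, 272 lower), among them all 64. The edgeR test called 46 (45 shared), 296 with the block, and DESeq2 1215. Moderation without trend and robust fitting gave 0 calls (2910 at an unadjusted p under 0.05, against 3208), as did each table alone (2407). The level of the dermal fibroblast list as a covariate gave 9 calls, 6 of them among the 64. All 64 kept their direction under each of these settings, but many of them could not turn it. Plain moderation, each table alone, sex as a block in limma and leaving out an untreated library do not alter the fold changes.

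Among the other genes with the largest rises, Tchhl1 was at 5.74 (SE 0.68) on the log2 scale, from 4 reads in each control to 117 and 668 in the labelled knockouts. Fam83a was at 3.14 (SE 0.24), the heparan sulfate sulfotransferase gene Hs3st1 at 2.90 (SE 0.42), the lipid transfer gene Pitpnc1 at 1.91 (SE 0.21), the water and glycerol channel gene Aqp3 at 1.87 (SE 0.23) and the tetraspanin gene Tspan3 at 1.75 (SE 0.22). Their adjusted p ran from 0.0221 to 0.0449. The largest falls outside the Lce1 genes were in Tnfsf15, a cytokine of the tumour necrosis factor family, at -3.40 (SE 0.34), Tmem177 at -3.31 (SE 0.33), Apol7a at -3.30 (SE 0.41), Tnfrsf11b at -3.11 (SE 0.32) and the noradrenaline transporter gene Slc6a2 at -2.77 (SE 0.39), with adjusted p of 0.0221 to 0.0439. Ap5b1 and Ehbp1l1, whose lower coordinates on chromosome 19 lie 18.9 kb and 158 kb above that of Ovol1, rose by a log2 fold change of 1.33 (adjusted p = 0.0439) and 1.34 (adjusted p = 0.0221). Of the 64 genes, 56 had the same sign in untreated epidermis, and 21 of those had an unadjusted p under 0.05 there.

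**Figure D2:**
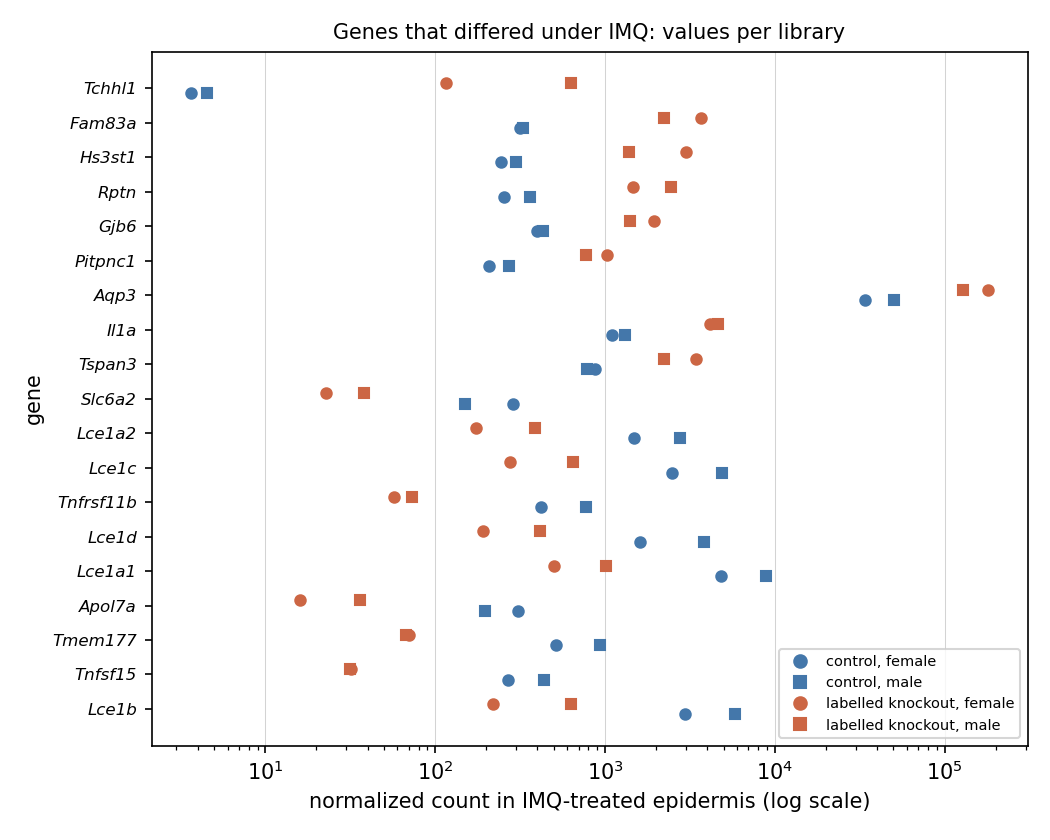
Normalised counts (log axis) in each of the 4 IMQ libraries for 9 genes with large rises and the 10 with the largest fall among the named genes past the threshold; circles are females and squares males. For each gene both labelled knockout libraries lie on 1 side of both controls, as for Il1a with group means of 1204 and 4376.

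The Lce and Sprr families of the epidermal differentiation complex split by subfamily under IMQ. All 14 tested Lce1 genes, within 92646535 to 93019060 on chromosome 3, had negative log2 fold changes, from -3.87 to -2.21 with a median of -3.16. The test called 5 of them lower: Lce1a1, Lce1a2, Lce1b, Lce1c and Lce1d. Adjusted over the list alone all 14 were lower, and with sex as a block 13 were. All 6 Lce3 genes were positive, from 1.70 to 3.04 with a median of 2.36, and 12 of 13 Sprr genes were positive with a median of 0.94. No Lce3 or Sprr gene was called over all genes, while 6 Lce3 and 3 Sprr genes were higher when adjusted over the list alone. Lce3e was at 3.04 (SE 0.60, limma adjusted p = 0.0714) and Sprr2f at 2.70 (SE 0.69, adjusted p = 0.105). Over the whole list the median was 0.62, the mean -0.52 and the camera direction down (adjusted p = 0.537), so the list as one was not called. Its median was 1.20 in the female pair and -0.15 in the male pair, so some Lce3 or Sprr genes were not higher in the male pair. In untreated epidermis the medians were -0.47 for Lce1, 0.74 for Lce3 and 0.18 for Sprr, and for the whole list the median was -0.19 and the mean 0.03. The subfamily medians kept their signs under the deposited scaling, TMM, quantile normalisation and CPM. In CPM, with an added 0.5, that of Lce3 was smaller, at 0.17 untreated and 1.85 under IMQ. The untreated Lce3 values include low counts: Lce3f had 2 reads in each control and 7 and 8 in the labelled knockouts. Lce1 and Sprr2 paralogs share sequence, so how reads were divided among members of a subfamily is uncertain.

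**Figure D3:**
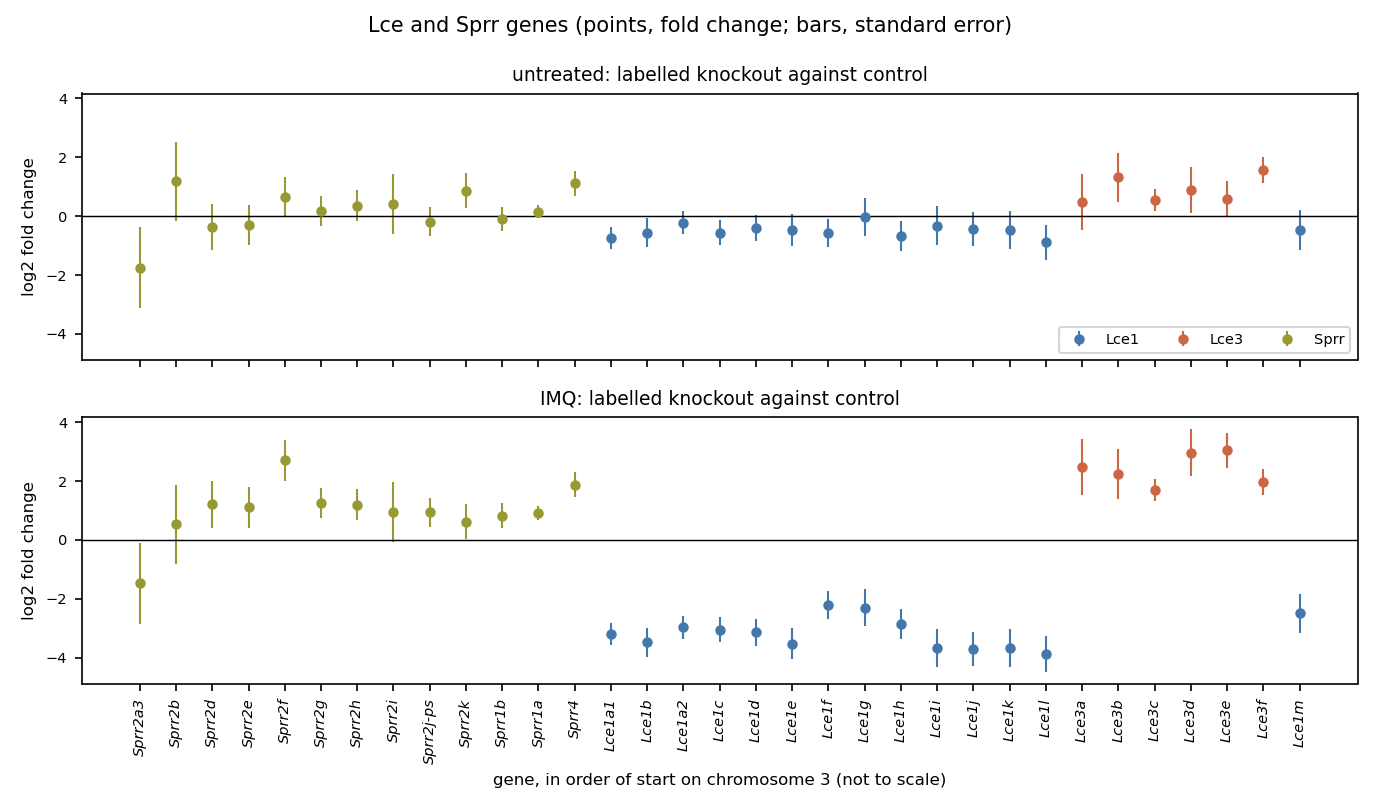
Log2 fold change of labelled knockout against control with its standard error for 33 Lce and Sprr genes in order along chromosome 3, untreated above and IMQ below. Under IMQ the 14 Lce1 genes lie between -3.87 and -2.21 and the 6 Lce3 genes between 1.70 and 3.04.

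Of the wider groups, 2 were called higher under IMQ and 5 lower with camera's preset correlation, while the adjusted p of each was 0.927 with an estimated correlation. The stress keratin and hyperproliferation list had 14 of 16 positive members and a median log2 fold change of 0.92, which was 1.49 in the female pair and 0.36 in the male pair (camera adjusted p = 7.50e-04, 0.0542 without the female control), with 1 member called higher, Gjb6, and 6 higher and 1 lower when adjusted over the list alone. The wound keratin gene Krt6b was at 3.33 (SE 0.91, limma adjusted p = 0.117), which was 1.72 without the female control and 4.93 (adjusted p = 0.0459) without the male control. Gjb2 was at 1.72 (SE 0.44, 0.105) and the growth factor gene Tgfa at 1.20 (SE 0.19, 0.0558, 0.0219 without the male labelled knockout). Neutrophil-attracting chemokines and growth factors had 6 of 7 positive members and a median of 1.23 (camera adjusted p = 0.0429, 0.0523 with quantile normalisation), with Cxcl2 at 1.54 (SE 0.38), Cxcl1 at 1.05 (SE 0.30) and Csf2 at 2.37 (SE 0.96). The call was lost without the female (0.0542) or male control (0.0971) or the female labelled knockout (0.110). None was called over all genes, and 2 were higher when adjusted over the list alone. The granular and cornified list had 20 of 24 negative members and a median of -0.39 (adjusted p = 0.0429, 0.413 without the male control and 0.344 without the female labelled knockout). The filaggrin-like gene Flg2 was at -1.72 (SE 0.37, limma adjusted p = 0.0818, 0.0123 with sex as a block and 0.0466 without the male labelled knockout) and Kprp, a proline-rich envelope protein gene, at -2.66 (SE 0.52, 0.0714, 0.0182 with the block and 0.0135 without that library), while Rptn was the 1 member called and was higher. Adjusted over the list alone, 1 was higher and 3 were lower.

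Interferon response genes were negative in 27 of 28 cases under IMQ with a median of -0.65 (camera adjusted p = 5.81e-04, 0.433 without the female control and 0.161 without the male labelled knockout), and the adjusted p was 0.927 with an estimated correlation for this and the next 3 lists. The antiviral genes Rsad2, Cmpk2 and Ifit2 were at -2.22 (SE 0.65), -1.80 (SE 0.52) and -1.76 (SE 0.55). Chemokines outside the neutrophil group had 17 of 22 negative members and a median of -0.75 (adjusted p = 0.0480), with Ccl6 at -2.58 (SE 0.71, limma adjusted p = 0.0307 without the male labelled knockout) and Cxcl13, an attractant of B cells, at -2.02 (SE 0.72). That call was lost without the female control (0.326), the male labelled knockout (0.0511) or the male untreated control (0.0511). Macrophage markers had 12 of 15 negative members and a median of -1.13, which was -1.81 in the female pair and -0.44 in the male pair (adjusted p = 0.0341, 0.205 without the female control and 0.132 without the female labelled knockout), with the mannose receptor gene Mrc1 at -2.12 (SE 0.75) and the complement gene C1qc at -1.86 (SE 0.51). The female control IMQ library also stood above the other 3 in the muscle gene Acta1 (52.4 against 1.58 to 8.58 CPM) and the endothelial gene Pecam1 (8.27 against 0.80 to 1.28). Dermal fibroblast markers were negative in 19 of 19 cases, with a median of -1.20 (adjusted p = 5.81e-04, 0.123 without the female labelled knockout) that was -1.71 in the female pair and -0.69 in the male pair. Pdgfra was at -1.97 (SE 0.74, limma adjusted p = 0.0486 without the male labelled knockout) and Col6a3 at -1.85 (SE 0.68). No member of these 4 lists was called over all genes. Adjusted over the list alone, macrophage markers had 1 higher and 3 lower and the other 3 lists had 0. The normalised count of Col1a1 was 1535 and 23561 in the female and male controls and 469 and 14839 in the labelled knockouts, so the sexes differed more than the genotypes.

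Several inflammatory genes were high in the labelled knockouts without passing the test. The keratinocyte cytokine genes Il24, Il19 and Il33 had log2 fold changes of 3.86 (SE 0.96, limma adjusted p = 0.102), 3.39 (SE 1.03, 0.132) and 2.20 (SE 0.42, 0.0714), and the calprotectin gene S100a8 was at 2.43 (SE 0.79, 0.153). Without the female control S100a8 was at 1.13 and Il19 at 2.02. The protease inhibitor gene Slpi was at 1.93 (SE 0.44, 0.0884). In the other direction, the cytokine gene Il17f was at -1.25 (SE 0.47, 0.190) and the defensin gene Defb14 at -1.76 (SE 0.40, 0.0881, 0.0216 with the block). The IL-1 family list had 1 member called higher, Il1a, 2 higher when adjusted over the list alone, and a median of -0.05 (camera adjusted p = 0.698). The antimicrobial list had a median of -0.13, which was 0.10 under quantile normalisation, and a mean of 0.14 (adjusted p = 0.946). The 27 lists not called had adjusted p of 0.0526 to 0.988, with cell cycle genes at the lower end (28 of 33 negative, median -0.39, 0.0452 with sex as a block). On recovered reads 11 lists were called and by fry 1, and without 1 library 3 to 11 were, with 3 without the female control and 11 without the male. The 3 short lists had medians of 0.03 for mast cells and basophils, -0.81 for haemoglobin genes and -0.33 for histones.

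**Figure D4:**
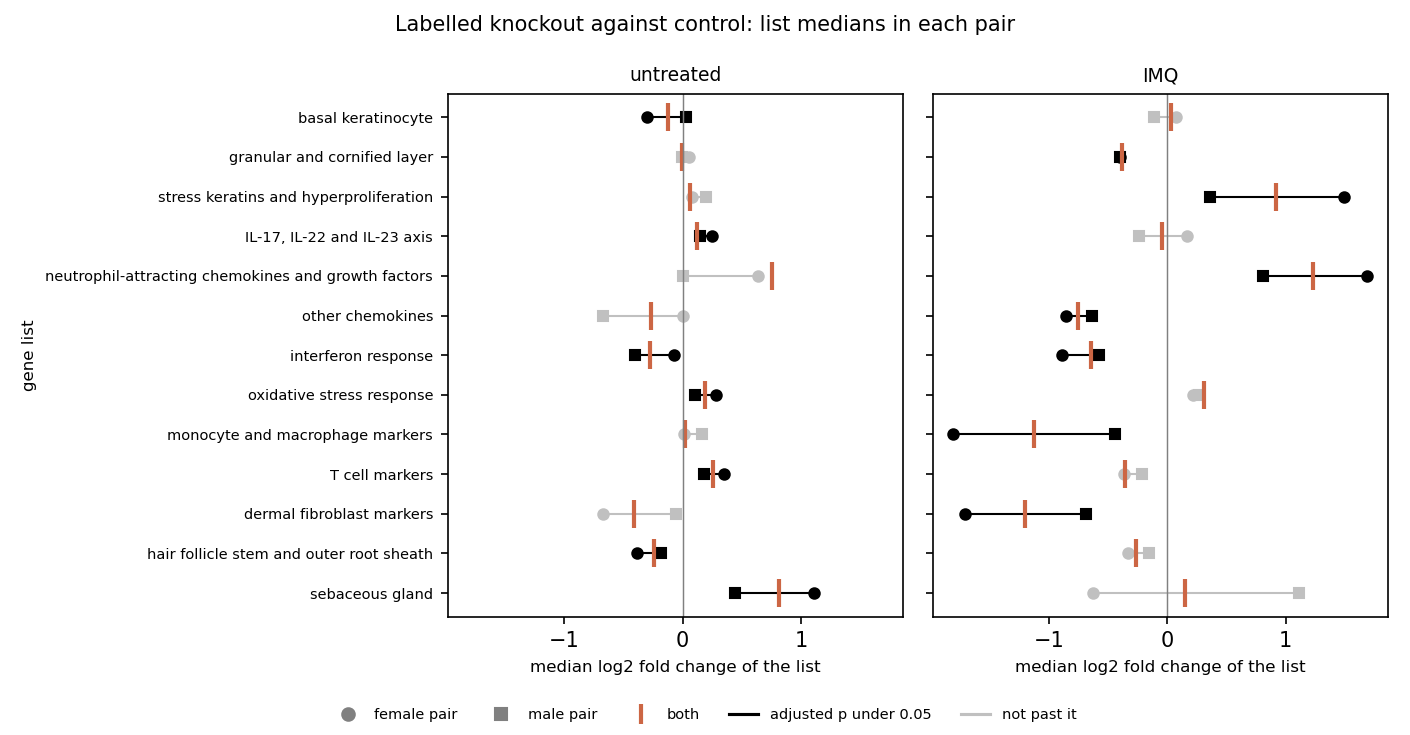
Median log2 fold change of labelled knockout against control for 13 gene lists in the female pair (circles), the male pair (squares) and both (bars), untreated at left and IMQ at right; black marks camera calls at an adjusted p under 0.05. The dermal fibroblast median under IMQ was -1.71 in females and -0.69 in males, and the medians near 0 changed sign between scalings for the granular and macrophage lists of untreated epidermis.

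The difference of the genotype effect between IMQ and untreated epidermis asks whether the effect depends on the treatment, with the change of control genotype inside it. With camera's preset correlation 5 lists were called, and with an estimated correlation the adjusted p of each was 0.939. With sex as a block the granular and cornified list was called as well (adjusted p = 0.00252, 0.0576 without the block). The stress keratin list had a genotype effect 0.84 higher under IMQ on the log2 scale in the median, 1.56 in females and 0.24 in males (camera adjusted p = 0.0168, 0.281 without the female control IMQ library). In contrast, T cell markers were at -0.56 (0.0152, 0.152 without the female untreated control) and macrophage markers at -1.08 (0.0168, 0.103 without the female control IMQ library and 0.0851 without the female labelled knockout IMQ library). Endothelial markers were at -2.18 (-2.68 in females and -0.53 in males, 0.0272), a call lost without the male untreated control (0.0722), the female untreated labelled knockout (0.0642), the female control IMQ library (0.369) or the male labelled knockout IMQ library (0.0741). Dermal fibroblast markers were at -0.80 (0.0339), a call lost without the female (0.0544) or male untreated control (0.0671), the male untreated labelled knockout (0.148), the male control IMQ library (0.332) or the female labelled knockout IMQ library (0.889). The genes with the smallest p in the upward direction were Fam83a at 3.14 (SE 0.34, limma adjusted p = 0.230), the pseudokinase gene Prag1 at 2.59 (SE 0.31, 0.230), Il1a at 1.72 (SE 0.25, 0.471), Pitpnc1 at 1.94 (SE 0.30, 0.476) and the phosphate transporter gene Slc20a2 at 0.96 (SE 0.19, 0.476). In the downward direction they were Itga9 at -4.82 (SE 0.56, 0.230), Skint8, of a family expressed in skin and thymus, at -2.23 (SE 0.31, 0.428), the catenin gene Arvcf at -1.04 (SE 0.15, 0.428), the choline dehydrogenase gene Chdh at -1.40 (SE 0.23, 0.476) and Alpk1 at -1.84 (SE 0.30, 0.476). Single Lce1 genes lay as low as Lce1i at -3.35 (SE 0.93, 0.476), with 10 Lce and Sprr genes lower when adjusted over the list alone.

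No gene passed the test of the difference: limma called 0 (1472 at an unadjusted p under 0.05, smallest adjusted p = 0.230), edgeR 0 (1534) and DESeq2 91 (34 higher, 57 lower). The 64 genes called under IMQ are therefore not shown to respond differently from untreated epidermis. Quantile normalisation called 10 lists and the recovered reads 9, fry 0, and 11 were called without the male library of either IMQ group or without the male untreated labelled knockout.

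Across 14614 genes the genotype effects in untreated and IMQ-treated epidermis correlated at a Pearson r of 0.255 (Spearman rho = 0.180), with r = 0.0583 in the female pairs and 0.281 in the male pairs. Within a treatment, the female and male effects correlated at 0.347 untreated and slightly higher under IMQ, so the effects repeated only in part between animals. Genes are not independent replicates, and r ran from 0.140 to 0.315 when 1 library was left out. Of 408 genes higher at an unadjusted p under 0.05 in untreated epidermis, 143 were also higher at that level under IMQ. Of 244 lower genes 99 were shared, while 30 genes passed in opposite directions. If the effects were independent, 40.9 higher and 29.1 lower genes would be shared. Both effects use 1 estimate of the spread per gene and so are not independent, and the counts are given without a test. Tchhl1, Gjb6 and Tmem177 were among the shared genes.

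IMQ-treated and untreated epidermis were set side by side as CPM (recovered reads scaled to a common library size), since the tables were scaled separately. Levels are given without a test, except by edgeR as an alternative. Interferon genes stood higher under IMQ in both genotypes, by a median log2 of 2.31 in the labelled knockouts and 2.84 in the controls, with at least a 2-fold rise in 27 and 28 of 28. Neutrophil chemokines stood higher by 4.37 and 2.87. Cxcl1 was 32.8-fold and 25.9-fold higher, Ccl20 51.6-fold and 19.3-fold. Stress keratins were higher by a median of 2.57 and 1.67, with Krt16 20.4-fold and 6.14-fold higher, and antimicrobial genes by 1.40 and 2.14. The 6.14-fold of Krt16 was 13.3-fold without the female and 2.83-fold without the male untreated control. S100a8 was 58.3-fold and 14.0-fold higher, S100a9 93.1-fold and 22.7-fold and Slpi 74.3-fold and 23.9-fold. Without 1 library those of the controls ran from 5.81 to 33.8 for S100a8, with the female and male control IMQ library left out at the upper and lower end, and from 9.38 to 54.9 for S100a9 with these libraries as well. In the labelled knockouts they ran from 39.4 to 86.4 for S100a8, 64.6 to 134 for S100a9 and 47.3 to 117 for Slpi, lowest without the male and highest without the female untreated library. Sebaceous genes were lower, at -1.34 and -0.85. Without 1 library their medians ran from -1.91 to -0.74 in the labelled knockouts and from -1.28 to -0.39 in the controls. Dermal fibroblast genes were at 0.13 and 1.15 and macrophage genes at 0.50 and 1.32. For the controls the fibroblast median was 0.17 without the male and 1.55 without the female IMQ library. In the labelled knockouts the fibroblast median was -0.81 without the male IMQ library, -0.26 without the female untreated library and 1.00 without the female IMQ library, and the macrophage median was 0.02 without the male IMQ library. At least 2-fold, 1716 genes were higher and 1908 lower in the labelled knockouts, against 1138 and 1029 in the controls, where the genotype differs between the tables (+/+ and +/-). The edgeR test called 3745 higher and 3491 lower in the labelled knockouts and 2541 and 1976 in the controls, with 2249 higher and 1764 lower in both and 3 in opposite directions. In the deposited values as they stand the median gene was shifted by -0.32 and -0.26 between the tables, and 3788 and 2533 genes were at least 2-fold lower.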

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

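The tests on the Lce1 genes, on the macrophage and endothelial markers, on the genes around Ovol1 and on an exchange of libraries, and the fibroblast covariate, were chosen after the result was seen. For 5 gene lists the test of the difference itself set the genotype effect under IMQ apart from that in untreated epidermis. On the log2 scale the median difference was 0.84 for stress keratins and hyperproliferation, -1.08 for monocyte and macrophage markers, -0.56 for T cell markers, -0.80 for dermal fibroblast markers and -2.18 for endothelial markers. With an estimated correlation none of the 5 held (adjusted p at least 0.939), and the control genotype (+/- untreated, +/+ under IMQ) is part of each difference.

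The first pattern is the genotype effect under IMQ, with Il1a, Gjb6 and Rptn among the 23 genes called higher and 5 Lce1 genes among the 41 called lower. A further-advanced IMQ response in the labelled knockout libraries may account for part of it: the genotype effect in 1 sex correlated across genes with the IMQ change of the controls of the other sex, at 0.346 and 0.136 (mean 0.241). For the 14 Lce1 genes a mere enlargement of the change seen in the controls is argued against. Their median IMQ change in the control pairs (+/+ IMQ against +/- untreated) was -0.40 in females and 0.58 in males, a largest size of 0.58. The labelled knockouts were at -3.18 and -1.69. A fall of Lce1 that begins only at a stage the controls had not reached cannot be tested with these libraries. An even loss across the genes of the granular and cornified list is also argued against as the whole cause for Lce1. The median of that list, -0.39 (camera adjusted p = 0.0429, 0.927 with an estimated correlation), lay 2.78 above that of Lce1. Its members were uneven, with 20 of 24 negative and 1 higher and 3 lower when adjusted over the list alone. A median cannot decide on a loss that falls on only some genes of the layer. The labelled genotype, litter and an IMQ exposure beyond the stage reached in the controls stay open for the Lce1 genes, untested.

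The second pattern is the negative medians of dermal, macrophage and endothelial markers in the labelled knockout IMQ libraries (Sparc of the fibroblast list also stands in another list, and keratinocyte expression of the markers was not tested). Less dermis in these libraries could lower all 3 lists. Of their 6 medians in the female and male pairs, 0 were above 0 (-1.71, -1.81 and -3.12 in females, -0.69, -0.44 and -0.15 in males). The 3 lists were chosen after their negative values were seen, so this count cannot decide on less dermis. The dispase step would remove most dermis, yet Col1a1 was at 765 CPM in the male control IMQ library against 50.3 in the female. Pecam1 (1.22 against 8.27) and Cd14 (32.6 against 60.4) ran the other way. In the labelled knockout IMQ libraries Pecam1 was at 0.80 and 1.28 CPM, near the male control. The lower Pecam1 in the labelled knockouts therefore rested on the female control library. These values do not decide on less dermis for macrophage and endothelial markers, and it stays open. Their medians lay furthest below 0 in the female pair. Those of skeletal muscle (-4.35) and adipocyte markers (-2.47) were also below 0 there, but were 1.03 and 0.47 in the male pair. For the 64 called genes the fibroblast level as a covariate cannot decide on less dermis as the cause. Their median absolute log2 fold change with it was 102% of that without (1.37 against 1.34). The covariate is fitted from differences between the female and the male of a group, which are small in genes that pass the test. In each group the fibroblast level was also higher in the male, so it cannot be told apart from sex. With the covariate only 9 genes were called. The median SE of the 64 went from 0.185 to 0.198 and the residual degrees of freedom from 4 to 3. A true change in dermal cells with genotype was not tested.

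The third pattern is the higher Ovol1 in the libraries labelled knockout, with the neighbours Ap5b1 and Ehbp1l1. An exchange of 1 labelled knockout and 1 control library within a table is argued against: within 1 sex it would oppose the female and male genotype effects, which correlated across genes at 0.347 untreated and slightly higher under IMQ, and across sexes it would move Xist and Ddx3y, which followed the labels. DNA of another strain around the targeted allele cannot be told apart from chance over a window of 20 Mb. Genes within it passed in both tables with an odds ratio of 1.83 (95% interval 0.772 to 3.71), with only 8 of 273 such genes against 233 of 14340 others. Of the 8, Trpm3 lay 16590 kb from Ovol1 and all others within 3260 kb. No narrower window was tested, so a local cluster stays open. A whole exchange of the genotype labels, and reads from a transcript of the targeted allele, were not tested.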

How the results depend on the processing

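The fibroblast covariate, the runs without 1 library with the block and those of IMQ against untreated were chosen after the result was seen. The 64 genes called under IMQ kept their direction under every alternative, which is no measure of stability. Other filters, plain moderation, each table alone, a block in limma or an untreated library left out do not alter the fold changes. Without an IMQ library, the small spread of called genes made a turn unlikely. The count of called genes was 60 to 69 with other pseudocounts, filters, TMM or quantile scaling, 46 with edgeR and 49 with a fold of at least 2. It was 0 with plain moderation and 0 with each table alone, 358 with sex as a block, 328 with sex by table, 296 with edgeR and the block, 1215 with DESeq2, 633 at an adjusted p under 0.10 and 9 with the fibroblast covariate. Without 1 library it ran from 0 to 299, and with the block it was 157, 154, 102 and 105 without an untreated library, 91 and 1306 without the female and male control IMQ library and 2 and 340 without the female and male labelled knockout IMQ library. The count in untreated epidermis, 0, went to 5 with a pseudocount of 5, 9 with quantile scaling, 8 with each table alone, 8 with sex as a block, 6 with edgeR and the block, 90 with DESeq2, 15 at an adjusted p under 0.10, 2 with the fibroblast covariate and 0 to 2 without 1 library. The difference had 0 genes under every setting except DESeq2, with 91. Leaving out libraries leaves fewer samples; for the other changes the cause was not tested.

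Of the lists, 7 were called in untreated epidermis, 7 under IMQ and 5 for the difference. An estimated correlation left 0, 0 and 0 and fry 0, 1 and 0. Sex as a block gave 11 for untreated epidermis, quantile scaling 10 for the difference, and recovered reads 11 under IMQ and 9 for the difference. Without 1 library the counts were 3 to 12, 3 to 11 and 4 to 11. Among results for single lists, 53 kept their call and 42 lost it in other settings, and 106 and 45 without 1 library, while the basal keratinocyte list of untreated epidermis turned up without the female control (adjusted p = 0.451, against 4.09e-07 to 0.473 without the others). For the correlation of effects r was 0.140 to 0.315 without 1 library and 0.303 with a mean of at least 50.

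For the genes chosen for naming, 1793 results in other settings kept their side of the threshold, 164 passed it newly, 87 lost it and 3 changed sign; without 1 library these were 995, 17, 175 and 5. Those that changed sign were differences near 0. The Ovol1 difference of -0.16 was 0.00216 without the male control IMQ library, the others giving down to -0.32. The Ovol2 difference of -0.03 was 0.0313 with quantile scaling, 0.0157 with DESeq2, 0.0678 with the fibroblast covariate and -0.33 to 0.27 without 1 library, being above 0 without the female untreated control (0.27), the male untreated labelled knockout (0.25), the female control IMQ library (0.11) and the female labelled knockout IMQ library (0.0325). The cause was not tested. IMQ against untreated, the deposited values as they stand gave 3788 lower genes in the labelled knockouts and 2533 in the controls in place of 1908 and 1029. The scaling differed, as did the added value (1 normalised count against 0.5 CPM). How much each of them gave was not tested. Without 1 library the labelled knockouts had 1607 to 1931 higher and 1629 to 2276 lower, and the controls 1128 to 1280 and 1006 to 1235. The edgeR test called 3745 higher and 3491 lower, and 2541 and 1976. Depth limits Tchhl1, Itga9, Il17a and Il17f, which had fewer than 10 reads in some library or few above it. The self-tests put 2-fold changes mostly below detection, but on simulated counts without a difference between the sexes.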

Other observations

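Among aryl hydrocarbon receptor targets under IMQ, Ahrr, the repressor of the receptor, rose by 1.68 on the log2 scale in labelled knockouts against controls (SE 0.21, limma adjusted p = 0.0356), and Cyp1b1 and Nqo1 were at 1.20 (SE 0.27, 0.0861) and 1.10 (SE 0.23, 0.0760), while the receptor gene Ahr was at -0.62 (SE 0.17, 0.121). The list had a median of 0.63 (camera adjusted p = 0.0526), with 1 of 6 members called and 3 higher and 1 lower when adjusted over the list alone. It was the 1 list that fry called under IMQ (adjusted p = 0.0451). In the hypoxia and glycolysis list Tpi1, a glycolytic enzyme gene, fell by 0.96 (SE 0.14, limma adjusted p = 0.0449), and Bnip3 and Pdk1 were at -1.49 (SE 0.29, 0.0714) and -0.96 (SE 0.19, 0.0742), against 0.94 (SE 0.19, 0.0734) for Hif1a. Without the male labelled knockout Pdk1 (0.0194) and Hif1a (0.0338) passed. That list had a median of -0.14 (camera adjusted p = 0.244), with 1 called lower of 18 and 1 higher and 3 lower when adjusted over the list alone. The oxidative stress list had a median of 0.31 (camera adjusted p = 0.0910), with Slc7a11, a cystine transporter gene, at 2.49 (SE 0.76, 0.135), Gsta4 at 1.61 (SE 0.42, 0.106) and the regulator Nfe2l2 at 0.74 (SE 0.20, 0.113).

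The epithelial junction list had a median of -0.02 (camera adjusted p = 0.741) with the tight junction gene Cgn at -2.05 (SE 0.49, limma adjusted p = 0.0934, 0.0382 with sex as a block and 0.0135 without the male labelled knockout) and the desmosomal gene Dsc2 at 1.07 (SE 0.18, 0.0605, 0.0398 with the block). Of genes outside the lists, the junction gene Arvcf fell by 1.18 on the log2 scale (SE 0.11, limma adjusted p = 0.0221) and Skint8 fell by 2.24 (SE 0.22, adjusted p = 0.0221). In the hair lists, Krt31, a hair shaft keratin gene, was at 16.7 and 21.2 normalised counts in the untreated groups, 4.80 in the IMQ controls and is listed at 0 in both labelled knockout IMQ libraries. Foxn1, a regulator of hair and keratinocyte differentiation, was at -0.93 (SE 0.24, 0.105) and the outer root sheath gene Fst at 0.97 (SE 0.23, 0.0915, 0.0430 with the block). The follicle stem list under IMQ had a median of -0.27 (camera adjusted p = 0.548).

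The female control IMQ library stood apart in genes of deeper tissue. In CPM, Acta1, a skeletal muscle actin gene, was at 52.4 in it and at 1.58 to 8.58 in the other 3 IMQ libraries, and Pecam1, an endothelial gene, was at 8.27 against 0.80 to 1.28. The skeletal muscle list had a median log2 fold change under IMQ of -4.35 in the female pair and 1.03 in the male pair (-1.28 over both, camera adjusted p = 0.0719), and the adipocyte list of -2.47 and 0.47. Mitochondrially encoded genes were negative under IMQ in 11 of 11 cases with a median of -0.34 (camera adjusted p = 0.216).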
